A study of Mus musculus with 8 samples.

How the data were processed

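RNA from 8 whole mouse placentas on a C57BL/6 background was measured, 1 placenta per array. Per the labels' protocols, each placenta was homogenised, its total RNA was column-purified, and Cy3-labelled cRNA was hybridised to an Agilent 1-colour expression array. The groups, taken from the sample titles, were wild type (WT, n = 2), placentas of normal-size embryos of transgenic females (dTG_normal, n = 3) and placentas of small embryos of transgenic females (dTG_small, n = 3). The series design text assigns the WT placentas to 1 dam and the 6 transgenic placentas to 2 dams, and no label gives the dam of a transgenic placenta. Genotype and dam therefore cannot be told apart, and p-values measure the spread between placentas, some of which shared a litter. The gestational age is not given in the sources used here.

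The deposited scanner files hold linear spot intensity values that Feature Extraction 11.0.1.1 had background-subtracted, and coordinates are on mm9, per the file headers. The value table deposited by the authors holds log2 values, and the submitters' processing notes name limma without a version. The scale of that table was found by setting each column against the scanner values, which gave slopes near 1, while its centring stays unknown and its values have no sign of a ratio. Its column medians were 4.71, 4.70, 4.70, 4.68, 4.76, 4.70, 4.72 and 4.69, in the order WT 1 and 2, dTG_normal 1 to 3 and dTG_small 1 to 3. Only 3 of its 8 columns matched best the scanner file of the sample they are named for. All main results rest on the scanner files and the table served as an alternative, though which labels are right stays open.

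Each array held 62976 spots, of which 59305 were not controls, with 55681 different probes. All 8 arrays lay on 1 slide and in 1 scan, in 2 lines of the slide. Both WT arrays lay at place 1 of their line, and the dTG arrays at places 2 to 4. Genotype and place on the slide therefore cannot be told apart, and a block by slide line does not correct for place. The share of non-control spots well above background ran from 52.0% to 58.4%, and no spot was saturated. The number of arrays, not a read depth, limits the precision: the median standard error of a log2 difference was 0.15 for dTG against WT.

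The processed signal was put on the log2 scale and each array's 75th percentile over non-control probes was subtracted, so levels are relative to that percentile. Control spots and outlier spots were left out, and spots of one probe were averaged. A probe was tested if it was well above background on at least 2 of the 8 arrays, which 32158 probes were. The probe with the highest mean level stood for its gene, and 6114 of the 23291 genes tested had several probes. Gene names came from the reference table of mouse genes, through the accession for 31845 spots, the symbol for 2264 and a synonym for 174; the array's own name was kept for 25022 spots, which can be old. Where a gene was not well above background on any array of a group, only a bound was given: "at least" folds compare the brighter group's mean with the mean of, per array, the higher of the lowest signal among probes well above background and the dim probe's own signal.

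All 8 arrays entered one 3-group limma model (lmFit and eBayes), so the comparisons share an estimate of the spread, and p-values were two-sided and adjusted by Benjamini-Hochberg over all genes tested, with 0.05 as the threshold. Errors given with ± are standard errors of that model. The 36 gene lists for placental and neighbouring cell types, pathways and gene families were written from general knowledge, without a literature source to check them against. They were fixed before the data were examined, as were the groups, the tests, the named-gene rule and most of the alternatives below. Of the lists, 34 had at least 5 tested genes. The Y-linked and X-inactivation lists had fewer and were given per array. The lists were tested with camera at a preset correlation of 0.01, adjusted over the 34 lists of a comparison. Camera with an estimated correlation and the rotation test fry were alternatives. Camera asks whether a list's genes changed more than the other genes, and fry whether they changed at all.

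The named genes are those with an adjusted p under 0.05, arrays that do not overlap between groups and a gene symbol as name. Of these the 12 highest and 12 lowest log2 differences were named for dTG against WT and for dTG_small against dTG_normal, and the 6 highest and 6 lowest for the comparisons of each transgenic group with WT. Where none passed in a direction, the 4 smallest unadjusted p in that direction were named as not passing. From each list whose test passed, the 4 members with the smallest unadjusted p were named, from other lists mentioned up to 2, and any member that passed.

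Alternatives fixed at that time were the median of each array, quantile normalization, normexp background correction (offset 50) with either scaling, other filters on dim probes, other ways to combine probes, only the groups compared in the fit, eBayes with trend and robust, array weights, the replicate number as a block, the Y-linked level as a covariate, the deposited value table, and leaving out each array. After the data were seen, 4 were added: the value table with its columns matched to scanner files, the slide line as a block, the yolk sac level of each placenta as a covariate, and probes with a CT repeat left out.

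The procedure was tested on simulated data, 20 sets of 23291 genes with 200 changed genes each. For dTG against WT, 57.9% of genes changed by a log2 of 1 and 85.8% of those changed by 2 were recovered, with a mean of 8.7 false calls. For dTG_normal against WT these were 50.6%, 83.0% and 7.1, for dTG_small against WT 49.6%, 79.6% and 8, and for dTG_small against dTG_normal 55.5%, 84.8% and 7.1. A list shifted by 1 was found in 20 of 20 sets in each comparison, with 4, 0, 5 and 3 false calls, in the same order, among 624 tests of other lists. Genes were drawn independently in these sets, so this rate of false calls does not carry over to lists whose genes vary together. R 4.3.3, limma 3.58.1, the data.table package at 1.17.8 and statmod 1.5.0 were used.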

Results

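Gene expression was measured in 8 mouse placentas: 2 from a wild-type female (WT) and 6 from 2 females carrying a human C19MC transgene (dTG). C19MC is a primate cluster of microRNA genes on human chromosome 19 that is active in the placenta. The transgenic placentas were split by embryo size into those of normal embryos (dTG_normal, n = 3) and of small embryos (dTG_small, n = 3). According to the series design, the size difference itself was not significant. The arrays measure mouse mRNA, so the level of the transgene's microRNAs was not analysed here. All levels are log2 values relative to the 75th percentile of an array, and ± gives the standard error of the limma model unless stated.

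Fetal sex differed between placentas. Ddx3y and Eif2s3y, genes of the Y chromosome, stood at 1.26 and 1.16 in dTG_normal replicate 2 and at 1.01 and 0.80 in dTG_normal replicate 3. On the other 6 arrays Ddx3y was between -6.99 and -6.23 and not well above background. Xist, which is expressed from the inactive X chromosome, had the opposite pattern, at -3.16 and -2.90 in those placentas and between 0.31 and 1.15 in the other 6. WT and dTG_small thus held no placenta with the Y-linked pattern, and the Y-linked genes named below follow this difference. Along component 1 of a principal component analysis (38.3% of variance) the WT placentas lay at -60.7 and -45.1 and the 6 dTG placentas between -3.78 and 50.9. Component 2 (21.6%) set dTG_small replicate 3, at 55.4, apart from the other 5 dTG placentas, at -24.6 to -9.10.

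**Figure D1:**
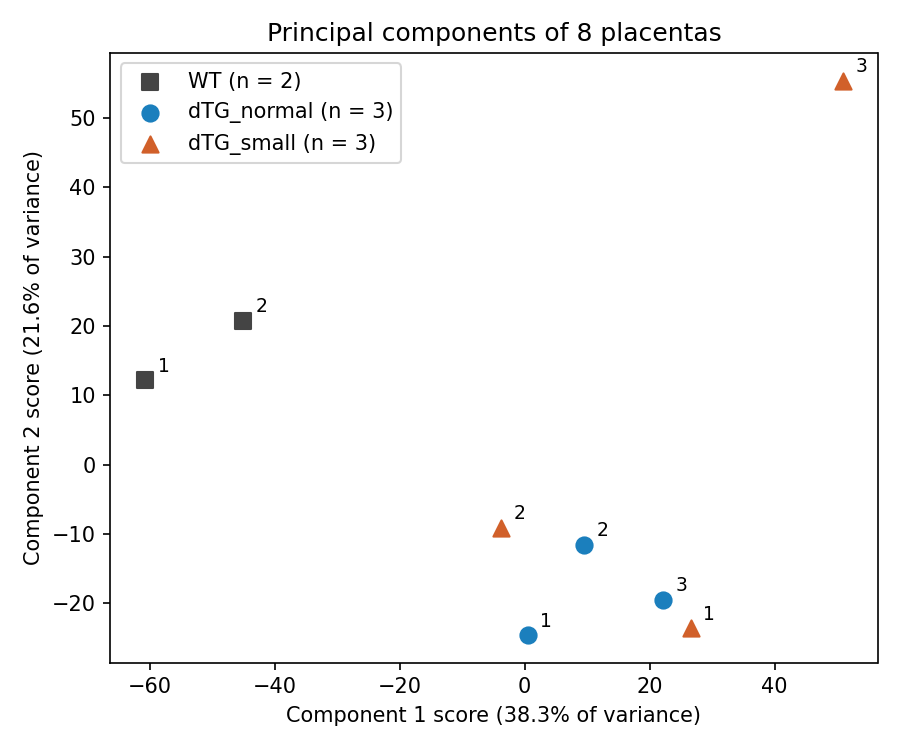
Each point is a placenta, placed by its scores on the leading pair of principal components of log2 levels (axes, unitless, with the percent of variance); squares are WT, circles dTG_normal and triangles dTG_small, and digits give the replicate. The WT placentas lie at -60.7 and -45.1 on component 1, below all 6 dTG placentas, and dTG_small replicate 3 lies at 55.4 on component 2.

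The first comparison asked how placentas of transgenic females differed from WT placentas. Hormone genes of the prolactin family changed both ways. Prl3c1 (2.45 ± 0.34; also in the decidua list), Prl7a2 (2.08 ± 0.31) and Prl7c1 (0.72 ± 0.14) rose, and Prl5a1 (-3.24 ± 0.24) and Prl3a1 (-1.80 ± 0.19) fell, in all 6 dTG placentas against both WT placentas. Single markers of the spongiotrophoblast and of glycogen cells, cell types of the junctional zone, rose, while Prl5a1 and Prl3a1 of the spongiotrophoblast list fell and neither list passed as a whole (camera adjusted p = 0.761 and 0.0744). The increase was 1.11 ± 0.12 for Tpbpa and 1.33 ± 0.18 for the imprinted regulator Ascl2. Among glycogen cell genes, Pcdh12 rose by 0.81 ± 0.087, Ncam1 by 1.36 ± 0.16 and Aldh1a3, an enzyme of retinoic acid synthesis, by 1.81 ± 0.24. Genes of the unfolded protein response and the pregnancy-specific glycoproteins were higher as lists, and genes of yolk sac endoderm, fetal endothelium and uterine smooth muscle were lower as lists at camera's preset correlation, and none of them passed with an estimated correlation (adjusted p = 0.776 for each). The limma test called 1412 of 23291 genes (n = 6 against 2), 1101 higher and 311 lower in dTG, 522 of them by at least 2-fold. The smallest adjusted p was 0.00083 and 6257 genes had an unadjusted p under 0.05. The direction of this split followed the scaling, as 78.0% of the calls were higher with the 75th percentile and 49.4% with the median of each array as the reference. The latter moved the median difference of all genes from 0.087 to -0.058.

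The largest upward difference was at the probe of Mc3r, a melanocortin receptor, at 3.90 ± 0.77 (limma adjusted p = 0.0367). Mmp1a, an interstitial collagenase whose probe lies on chromosome 9 from 7476795 to 7476854, rose by 3.53 ± 0.32 (adjusted p = 0.00798). The probes of the olfactory receptor Olfr1466 (3.46 ± 0.71), the bitter taste receptor Tas2r113 (3.22 ± 0.72) and the orphan receptor Gpr157 (2.53 ± 0.50) were also higher. These probes and that of Mc3r contain repeats of the bases C and T (TCTCTC), so whether the 4 transcripts rose is not settled. Over 26 alternatives, the calls of Mc3r, Olfr1466, Tas2r113 and Gpr157 were lost in 11, 13, 17 and 12. Of the 12 named rises, that of Mmp1a was the largest without TCTCTC in its probe. The homeobox gene Cux2, the catenin gene Ctnna2, Stpg4 and Glp2r, a receptor of a gut peptide, were not well above background in WT and were at least 3.26-fold, 4.55-fold, 2.48-fold and 1.96-fold higher in dTG (limma adjusted p = 0.00673, 0.0138, 0.00798 and 0.0171). The other Glp2r probe gave a log2 difference of 0.79. Mlc1, a membrane protein gene of astrocytes, rose by 2.96 ± 0.28 and Spag5, a mitotic spindle gene, by 2.62 ± 0.20. In the other direction, Tph1, the rate-limiting enzyme of peripheral serotonin synthesis, fell by 3.32 ± 0.67 (adjusted p = 0.0378), and the serotonin receptor gene Htr1d by 2.19 ± 0.17. Prl5a1, whose probe lies on chromosome 13 from 28243046 to 28243105, had an adjusted p of 0.00556. Doxl1 fell by 3.12 ± 0.22, Sod3, an extracellular superoxide dismutase, by 2.52 ± 0.19, Ttn, the sarcomere protein titin, by 2.42 ± 0.51, and Ube2ql1 by 2.38 ± 0.15. Rab17, a small GTPase gene, fell by 2.22 ± 0.46 (other probe -1.25) and Atp10d, a lipid flippase gene, by 2.11 ± 0.21. The homeobox gene Hmx3, Mrap2, which encodes a partner of melanocortin receptors, and Dydc2 were not well above background in dTG and were at least 2.00-fold, 2.51-fold and 1.59-fold lower.

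**Figure D2:**
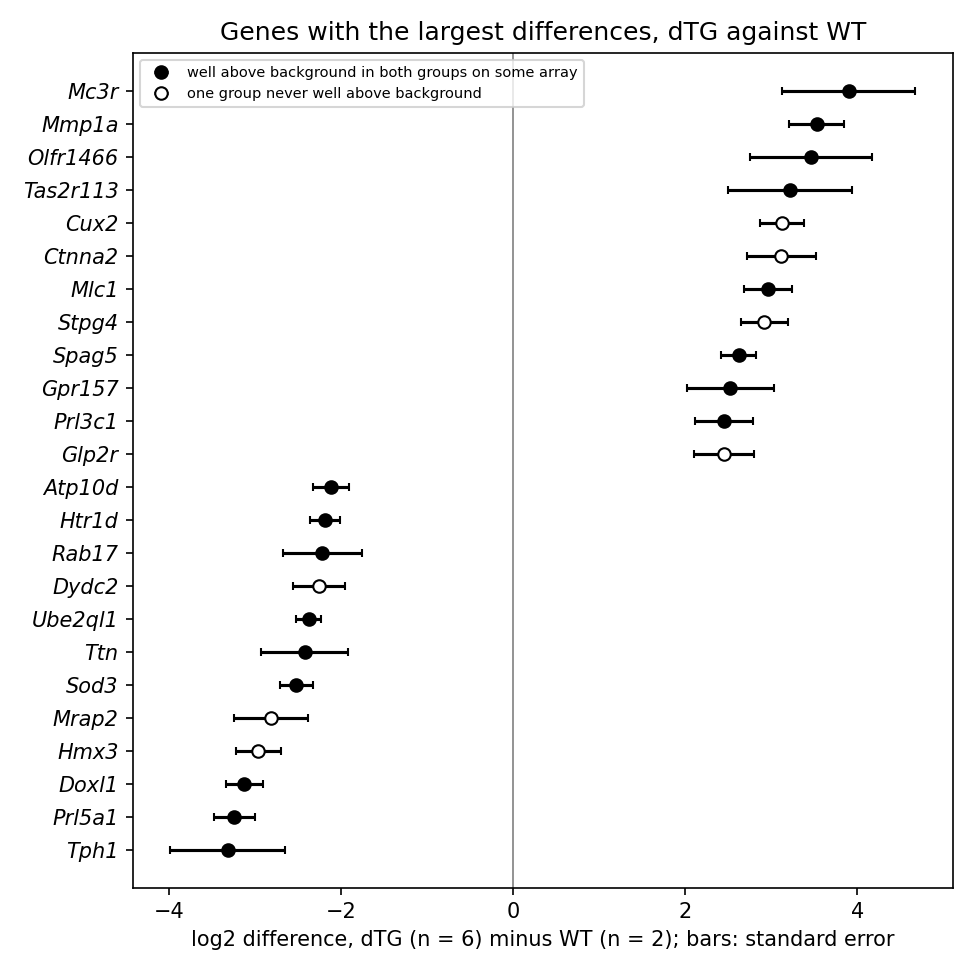
Points give the log2 difference of each named gene, the mean of 6 dTG minus the mean of 2 WT placentas (horizontal axis), and bars its standard error; open points mark genes with a group that was not well above background on any array. The differences run from -3.32 for Tph1 to 3.90 for Mc3r.

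Of the 34 lists, 7 shifted with camera at the preset correlation, 2 upward and 5 downward. In the unfolded protein response list, 8 of 18 genes rose and none fell, with a median of 0.50 (adjusted p = 0.00107). Of these genes, 14 passed when adjusted over the list alone, 13 higher and 1 lower. Its members include the endoplasmic reticulum proteins Creld2 (1.21 ± 0.14), Sdf2l1 (1.06 ± 0.18) and Manf (0.79 ± 0.18), the chaperones Hsp90b1 (0.52 ± 0.10), Calr (0.71 ± 0.15) and Dnajc3 (0.44 ± 0.095), the disulfide isomerase Pdia4 (0.81 ± 0.16) and Trib3 (0.62 ± 0.13). In the pregnancy-specific glycoprotein list (22 genes, median 0.42, adjusted p = 0.0013), Ceacam9 (2.20 ± 0.42), Ceacam14 (0.84 ± 0.14), Psg17 (0.83 ± 0.16), Psg19 (0.80 ± 0.17) and Psg28 (0.56 ± 0.10) rose and Psg22 fell by 1.22 ± 0.20. Adjusted over the list alone, 14 were higher and 1 lower. All 19 genes of the yolk sac endoderm list had values below 0, with a median of -1.87 (adjusted p = 3.49e-09). Hnf4a, a regulator of endoderm, fell by 1.61 ± 0.33, while the serum protein genes Apob (-2.21 ± 0.57), Apoc2 (-2.15 ± 0.72) and Trf (-0.92 ± 0.25) did not pass over all genes. In this list 3 were lower when adjusted over the list alone. The mean of this list relative to WT was -3.51, -0.98 and -2.24 in dTG_normal replicates 1 to 3 and -2.15, -1.40 and -0.94 in dTG_small replicates 1 to 3, against -0.11 and 0.11 in WT.

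The fetal endothelium list (median -0.46, adjusted p = 0.00123) had 19 of 20 genes below 0 and none that passed, or passed adjusted over the list alone. Sox17 was at -0.54 ± 0.20, Sox7 at -0.74 ± 0.33 and the endoglin gene Eng at -0.49 ± 0.22, and the exception, Cdh5, at 0.31 ± 0.10. Without dTG_small replicate 3 the median of this list was -0.29. All 9 uterine smooth muscle genes were below 0 (median -0.69, adjusted p = 0.0127), with none that passed under either adjustment. The contractile genes Cnn1, Synpo2, Actg2 and Tagln were at -1.56 ± 0.79, -1.09 ± 0.47, -0.98 ± 0.50 and -0.65 ± 0.38. The smooth muscle median was -0.22 without WT replicate 1 and -1.28 without WT replicate 2. The decidua list (16 genes, median -0.15, adjusted p = 0.0362) was lower although its 1 passing gene, Prl3c1, rose. Wnt4 was at -0.88 ± 0.21, Il15 at -0.85 ± 0.23 and Igfbp3 at -0.50 ± 0.16, and adjusted over the list alone 1 was higher and 2 were lower. The imprinted list (33 genes, median -0.24, adjusted p = 0.0391) was lower too, although its 3 passing genes rose. These were Ascl2, the amino acid transporter gene Slc38a4 (0.93 ± 0.10) and Sfmbt2 (0.67 ± 0.15), while Meg3 was at -0.75 ± 0.20. Adjusted over the list alone, 3 were higher and none lower. Without dTG_small replicate 1 the decidua median was -0.073, and without WT replicate 2 the imprinted median was -0.39. With an estimated correlation none of the 7 lists passed (adjusted p = 0.776 for each). The unfolded protein response list also passed with fry (adjusted p = 0.0284). So did 3 lists that camera did not call, trophoblast stem cells (0.00569), glycogen trophoblast (0.00743) and hypoxia and glycolysis (0.0334). Fry does not set a list against the other genes, so passing it shows no shift particular to a list.

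The other 27 lists did not pass. Median log2 differences were 0.15 for spongiotrophoblast, 0.23 for glycogen trophoblast, 0.25 for giant cells, 0.35 for the prolactin family, 0.15 for placental cathepsins and 0.40 for trophoblast stem cells. They were -0.26 for labyrinth syncytiotrophoblast, 0.031 for stroma, -0.18 for uterine natural killer cells, 0.22 for macrophages and leukocytes and -0.37 for erythroid cells. For processes they were 0.10 for the cell cycle, 0.20 for hypoxia and glycolysis, -0.0036 for angiogenic factors, -0.26 for nutrient transport, 0.037 for cholesterol synthesis, 0.016 for steroid hormone synthesis, 0.13 for interferon-stimulated genes and 0.29 for inflammation. They were 0.042 for autophagy, -0.036 for the microRNA pathway, -0.0063 for migration, -0.040 for apoptosis, -0.070 for immediate early genes, 0.032 for heat shock, 0.13 for ribosomal proteins and 0.14 for oxidative phosphorylation. Camera pointed down where the median was above 0 for stroma, the cell cycle, steroid synthesis, interferon-stimulated genes, inflammation, autophagy and heat shock. The mean was also below 0 for stroma and steroid synthesis, and it was 0.028 for migration, whose median and test were down. Many of these medians rested on dTG_small replicate 3. Without it, the median was -0.058 for inflammation, -0.12 for stroma and 0.015 for angiogenic factors, each of the opposite sign. It was 0.12 for giant cells, 0.15 for the prolactin family, -0.11 for labyrinth, -0.52 for natural killer cells, 0.064 for leukocytes and -0.074 for erythroid cells. It was 0.039 for the cell cycle, 0.0048 for cholesterol synthesis, 0.026 for autophagy, -0.071 for migration, -0.14 for immediate early genes and 0.0066 for heat shock. The medians of stroma, the cell cycle, cholesterol and steroid synthesis, interferon-stimulated genes, autophagy, heat shock, ribosomal proteins and oxidative phosphorylation turned negative with the median of each array as the reference.

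Genes that passed in these lists were, among leukocyte markers, the class II genes H2-Aa (0.99 ± 0.18) and H2-Ab1 (0.76 ± 0.17), Cd68 (0.88 ± 0.16) and the receptor gene Csf1r (0.50 ± 0.11), with Il2rb (0.95 ± 0.17) of the natural killer list. The trophoblast genes Id2 (0.72 ± 0.13), Tfap2c (0.63 ± 0.13) and Ctsm (0.78 ± 0.14), the chemokine gene Cxcl12 (1.04 ± 0.10), Angpt4 (1.01 ± 0.21), Hsd17b7 of cholesterol synthesis (0.95 ± 0.19) and the glycolysis and hypoxia genes Pfkp (0.75 ± 0.14), P4ha1 (0.47 ± 0.086) and Hk2 (0.45 ± 0.089) rose. The other probes of Angpt4 gave -0.34 and -0.19. Pdgfra rose by 0.45 ± 0.10 and Thy1 fell by 1.15 ± 0.23, and Ermap, an erythroid membrane gene, rose by 1.28 ± 0.24 (other probe 0.050). The interferon genes Ifi47 (-0.85 ± 0.19), Irf1 (-0.55 ± 0.12) and Oasl1 (-0.49 ± 0.11), Tnfaip3 (-0.41 ± 0.089) and Cdkn1a (-0.50 ± 0.11) fell. Adjusted over the list alone, 5 spongiotrophoblast genes were higher and 2 lower, and 4 prolactin-family genes were higher and 2 lower. By the same adjustment 4 glycogen trophoblast, 5 hypoxia and glycolysis, 4 leukocyte, 3 trophoblast stem cell, 3 cholesterol synthesis and 2 cathepsin genes were higher, and 3 interferon-stimulated genes were lower. Cdkn1a, of the apoptosis list, did not pass that way.

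Genotype, dam and place on the slide cannot be told apart here. The yolk sac level itself separated the groups (WT -0.11 and 0.11, dTG -3.51 to -0.94), so as a covariate it takes up much of the genotype difference. The Y-linked level was high only in dTG_normal replicates 2 and 3. As a covariate it leaves the dTG_normal mean resting mainly on replicate 1. A lower count with it therefore does not show that fetal sex made the difference. The count of 1412 genes was 1 with the yolk sac level as a covariate and 94 with the Y-linked level. It was 815 with the slide line as a block and 416 without a filter on dim probes. It was 15, 194, 509, 341 and 549 without WT replicate 1, WT replicate 2, dTG_normal replicate 2, dTG_normal replicate 3 and dTG_small replicate 1. The smooth muscle call ended without WT replicate 1 (adjusted p = 0.187), the imprinted call without WT replicate 1 (0.108), WT replicate 2 (0.0683), dTG_normal replicate 3 (0.0593) or dTG_small replicate 1 (0.0531). The decidua call ended without WT replicate 1 (0.0627), WT replicate 2 (0.0790), dTG_normal replicate 2 (0.0583) or dTG_small replicate 1 (0.0983). These 3 calls ended with the median of each array (0.0748, 0.0912 and 0.0912), and the pregnancy-specific glycoprotein call with the yolk sac covariate (0.0599).

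The second comparison set placentas of normal-size embryos of transgenic females against WT. Mmp1a (3.58 ± 0.36) and Mlc1 (3.12 ± 0.31) rose most among genes measured in both groups, and Cux2, Ctnna2, Stpg4 and Glp2r (other probe 0.65) were at least 3.996-fold, 4.71-fold, 2.71-fold and 2.37-fold higher. Prl5a1 (-3.84 ± 0.27), Doxl1 (-3.58 ± 0.24), Sod3 (-2.71 ± 0.22) and Ube2ql1 (-2.57 ± 0.16) fell, and Mrap2 and Hmx3 were at least 2.10-fold and 1.68-fold lower. In the junctional zone and hormone lists, Tpbpa (1.06 ± 0.13), Ascl2 (1.18 ± 0.20), Pcdh12 (0.79 ± 0.098), Ncam1 (1.32 ± 0.18), Aldh1a3 (1.68 ± 0.27), Prl7a2 (2.06 ± 0.35) and Prl3c1 (2.50 ± 0.38) rose and Prl3a1 fell by 2.03 ± 0.21. The limma test called 539 genes (n = 3 against 2), 409 higher and 130 lower, with 4993 at an unadjusted p under 0.05. Of the calls, 75.9% were higher, or 52.9% with the median of each array. Also passing were Cd68 (1.03 ± 0.18), Slc38a4 (0.99 ± 0.12), Cxcl12 (0.99 ± 0.11), Id2 (0.79 ± 0.15) and, downward, Oasl1 (-0.67 ± 0.12).

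In this comparison 5 lists shifted. The yolk sac endoderm list had a median of -2.41 (camera adjusted p = 1.57e-11). Of its 19 genes, 17 were lower when adjusted over the list alone and none over all genes. Hnf4a was at -1.72 ± 0.37, Apob at -2.50 ± 0.64, Trf at -1.02 ± 0.28 and the albumin gene Alb at -3.48 ± 1.03. The unfolded protein response list (median 0.50, adjusted p = 0.000511) had 1 passing gene, Creld2 (1.14 ± 0.15), with 11 higher when adjusted over the list alone. Sdf2l1 was at 0.96 ± 0.20, Hsp90b1 at 0.50 ± 0.12 and Calr at 0.72 ± 0.17. Among pregnancy-specific glycoproteins (median 0.42, adjusted p = 0.000511), Ceacam14 rose by 0.85 ± 0.16 and Psg22 fell by 1.56 ± 0.22. Psg17 and Psg28 were at 0.89 ± 0.17 and 0.58 ± 0.11, and 13 were higher and 1 lower adjusted over the list alone. The endothelium list (median -0.29, adjusted p = 0.0372; Sox17 -0.40 ± 0.22, Cldn5 -0.32 ± 0.20, Egfl7 -0.26 ± 0.18, and Cdh5 at 0.30 ± 0.12) had no passing gene under either adjustment. The hypoxia and glycolysis list (median 0.23, adjusted p = 0.0495) had 1, P4ha1 (0.51 ± 0.096), with Pfkp at 0.72 ± 0.15, Hk2 at 0.40 ± 0.10 and Bnip3l at 0.37 ± 0.10, and 3 higher adjusted over the list alone. With an estimated correlation none of the 5 passed (adjusted p = 0.831 for each), and with fry 2 of them did, the unfolded protein response and the hypoxia list. The count of 539 genes was 18, 79, 20 and 31 without WT replicate 1, WT replicate 2, dTG_normal replicate 2 and dTG_normal replicate 3, 9 with the Y-linked level and 0 with the yolk sac level as a covariate. The endothelium call ended without WT replicate 1 (adjusted p = 0.144), dTG_normal replicate 3 (0.0987) or dTG_small replicate 1 (0.0517). The hypoxia call ended without WT replicate 1 (0.1996), dTG_normal replicate 3 (0.0987), dTG_small replicate 1 (0.0564) or dTG_small replicate 2 (0.0767). Both ended with the median of each array (0.134 and 0.135). The glycoprotein call ended with the yolk sac covariate (0.0662).

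The third comparison set placentas of small embryos of transgenic females against WT. Mmp1a (3.48 ± 0.36), Mlc1 (2.81 ± 0.31) and Spag5 (2.58 ± 0.22) rose, and Ctnna2, Cux2 and Stpg4 were at least 4.39-fold, 2.67-fold and 2.28-fold higher. Doxl1 (-2.67 ± 0.24), Prl5a1 (-2.64 ± 0.27) and Sod3 (-2.33 ± 0.22) fell, and Hmx3, Mrap2 and Prok1, which encodes a secreted prokineticin, were at least 2.39-fold, 2.99-fold and 1.83-fold lower. Of 12 glycogen trophoblast genes, 3 rose (Pcdh12 0.84 ± 0.098, Ncam1 1.41 ± 0.18 and Aldh1a3 1.94 ± 0.27). The list passed at the preset correlation (adjusted p = 0.0436), but not with an estimated one (0.803), and it was kept on leaving out 3 of the 8 placentas. The hormone and junctional zone genes Prl7a2 (2.11 ± 0.35), Prl3c1 (2.40 ± 0.38), Prl7c1 (0.96 ± 0.16), Ascl2 (1.49 ± 0.20) and Tpbpa (1.15 ± 0.13) rose while Prl3a1 fell by 1.57 ± 0.21. The limma test called 654 genes (n = 3 against 2), 501 higher and 153 lower, with 6032 at an unadjusted p under 0.05. Of the calls, 76.6% were higher, or 46.9% with the median of each array. Slc38a4 (0.88 ± 0.12), Cxcl12 (1.09 ± 0.11), H2-Aa (1.11 ± 0.20), Hsd17b7 (1.04 ± 0.21) and Ermap (1.35 ± 0.27) also passed.

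Here 10 lists shifted. Downward were yolk sac endoderm (median -1.65, camera adjusted p = 3.88e-06; Hnf4a -1.50 ± 0.37, Apob -1.92 ± 0.64, Trf -0.82 ± 0.28, Apoc2 -1.73 ± 0.81), endothelium (-0.64, 0.000164; Sox17 -0.68 ± 0.22, Sox7 -0.99 ± 0.37, Eng -0.67 ± 0.25, with Cdh5 at 0.31 ± 0.12), and smooth muscle (-1.02, 0.0057; Synpo2 -1.19 ± 0.52, Cnn1 -1.83 ± 0.89, Mylk -1.02 ± 0.50, Actg2 -1.02 ± 0.56). None of their genes passed, over all genes or adjusted over the list alone. Labyrinth syncytiotrophoblast, the exchange layer between the maternal and fetal blood, was lower as a list (median -0.32, adjusted p = 0.0436) with no passing gene under either adjustment. Gcm1, its master regulator, was at -0.76 ± 0.29, Tead3 at -0.45 ± 0.17, Cebpa at -0.41 ± 0.18 and the lactate transporter gene Slc16a1 at 0.53 ± 0.25. Nutrient transport (-0.28, 0.0258) was lower although its 1 passing gene, Slc38a4, rose, with Slc19a1 at 0.25 ± 0.093 and Slc38a1 at 0.28 ± 0.12. In this list 1 was higher adjusted over the list alone. Imprinted genes (-0.32, 0.0157) were lower as a list while Slc38a4 and Ascl2 rose. Meg3 was at -0.92 ± 0.22 and Sfmbt2 at 0.67 ± 0.17, and 3 were higher and 1 lower adjusted over the list alone. In the decidua list (-0.14, 0.0258), Prl3c1 rose and Bmp2, Wnt4 and Il15 were at -0.47 ± 0.13, -0.90 ± 0.24 and -0.75 ± 0.26, with 1 higher and 2 lower adjusted over the list alone. Upward were the unfolded protein response (median 0.49, adjusted p = 0.00106; Creld2 1.28 ± 0.15, Sdf2l1 1.16 ± 0.20, Pdia4 0.95 ± 0.18 and Trib3 0.74 ± 0.14 rose), the pregnancy-specific glycoproteins (0.42, 0.0057; Ceacam14 rose by 0.83 ± 0.16, with Ceacam9 at 2.34 ± 0.47, Psg19 at 0.90 ± 0.19 and Psg28 at 0.53 ± 0.11) and glycogen trophoblast (0.30, 0.0436; the further member Gbe1 was at 0.51 ± 0.14). Adjusted over the list alone, 11 genes were higher and 1 lower in each of the former pair, and 4 were higher in the glycogen list. With an estimated correlation none of the 10 passed (adjusted p = 0.803 for each).

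The count of 654 genes was 3, 65, 71, 199, 20, 1031 and 113 without WT replicates 1 and 2, dTG_normal replicates 2 and 3 and dTG_small replicates 1, 2 and 3, 2 in a fit of only these groups and 5 with the yolk sac covariate. Without dTG_small replicate 3 the medians were -0.29 for endothelium, -0.52 for smooth muscle, -0.066 for labyrinth, -0.14 for nutrient transport, -0.20 for imprinted genes and -0.28 for decidua. Without WT replicate 1 they were -0.41 for smooth muscle and -0.21 for imprinted genes, and without dTG_small replicate 1 the decidua median was -0.044. Without dTG_small replicate 3 the labyrinth (adjusted p = 0.546), nutrient transport (0.190), imprinted (0.0769) and glycogen (0.0769) calls ended. The labyrinth call also ended without WT replicate 1 (0.0921), WT replicate 2 (0.0549), dTG_normal replicate 1 (0.0526) or dTG_normal replicate 2 (0.0572). The glycogen call ended without WT replicate 2 (0.0573) or dTG_normal replicates 1 (0.0668), 2 (0.0575) or 3 (0.0572). The nutrient transport call ended without WT replicate 2 (0.0549), decidua without WT replicate 2 (0.0674) or dTG_small replicate 1 (0.204), smooth muscle without WT replicate 1 (0.0902), and the glycoprotein call with the yolk sac covariate (0.0615).

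Both transgenic groups were set against the same WT placentas. Their log2 differences correlated across genes at 0.842, against 0.602 in 20 simulations of unchanged groups with shared controls. The covariance was 0.212 against 0.0595 simulated. In both comparisons 315 genes were higher and 97 lower, and none was opposite. These counts have no simulated value to set them against. With a separate WT placenta for each transgenic group, the covariance was 0.177 with WT replicate 1 for dTG_normal and WT replicate 2 for dTG_small, and 0.163 the other way round (correlations 0.618 and 0.549). These WT placentas shared a dam, and genes are not independent replicates.

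The fourth comparison asked whether, in transgenic females, placentas of small embryos differed from those of normal-size embryos. No gene passed: limma called 0 of 23291 genes, with 776 at an unadjusted p under 0.05 and a smallest adjusted p of 0.985. The genes with the smallest unadjusted p, none passing, were Serpina3i, a serine protease inhibitor gene (at least 1.35-fold higher, measured on 2 of 3 dTG_small arrays; other probe 0.26), the endothelin gene Edn2 (0.87 ± 0.16), Dop1a (0.51 ± 0.096; other probe -0.22) and Prl5a1 (1.21 ± 0.24) on the higher side. On the lower side they were Cfap57 (-0.89 ± 0.14), the potassium channel gene Kcnt1 (-0.85 ± 0.18), Fbxw21 (-0.62 ± 0.15) and the Y-linked Eif2s3y (at least 16.7-fold lower in dTG_small, measured on 2 of 3 dTG_normal arrays). With an adjustment over the list alone, 1 gene each was higher in the spongiotrophoblast, prolactin and steroid synthesis lists.

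By list, 5 shifted between the transgenic groups at camera's preset correlation. Every other even split of the dTG placentas gave more lists (9 to 17), so this count is no evidence of a difference by embryo size. Cell cycle genes were higher in dTG_small (median 0.17, camera adjusted p = 0.000116), with 20 of 22 above 0. Mcm5 and Mcm3 of the replication helicase were at 0.52 ± 0.19 and 0.26 ± 0.14, Top2a at 0.49 ± 0.19 and Ccnb2 at 1.07 ± 0.49. Interferon-stimulated genes were higher (median 0.20, adjusted p = 0.000374), with Gbp2 at 0.45 ± 0.13, Oasl1 at 0.36 ± 0.11, Mx2 at 0.55 ± 0.28 and Psmb9 at 0.21 ± 0.12. Yolk sac endoderm genes were higher (median 0.92, adjusted p = 0.000528), with Alb at 1.83 ± 0.92, Ttr at 1.13 ± 0.81, Amn at 1.09 ± 0.78 and Apoa2 at 0.92 ± 0.67. Inflammation genes were higher too (0.44, 0.00406), with Il6 at 1.39 ± 0.51, Il1rn at 0.54 ± 0.24, Il1b at 0.91 ± 0.52 and Tnfaip3 at 0.15 ± 0.089. Endothelial genes were lower (median -0.31, adjusted p = 0.00135), with Esam at -0.30 ± 0.13, Erg at -0.58 ± 0.32 and Eng at -0.36 ± 0.22, and Cldn5 at 0.29 ± 0.18. No gene of these 5 lists passed, over all genes or adjusted over the list alone, and with an estimated correlation none of the lists passed (adjusted p = 0.858 for each). Without dTG_small replicate 3 the yolk sac (adjusted p = 0.0985), inflammation (0.168, then downward) and endothelium (0.907) calls ended. The medians without it were 0.48, -0.22 and -0.030, and 0.10 for the cell cycle. The yolk sac median was 0.18 without dTG_normal replicate 1 and 1.62 without dTG_normal replicate 2, and the cell cycle median 0.092 without dTG_normal replicate 3. Without dTG_small replicate 1 the interferon median was 0.091 and the inflammation median 0.82, and without dTG_small replicate 2 the interferon median was 0.31 and the endothelium median -0.55. The yolk sac call also ended without dTG_normal replicate 1 (0.549). Other losses were the cell cycle (0.0734), interferon (0.0615) and inflammation (0.0734) calls without dTG_normal replicate 3, and the interferon call without dTG_small replicate 1 (0.0631). With the Y-linked level as a covariate the cell cycle (0.626), interferon (0.741), inflammation (0.626) and endothelium (0.0964) calls ended. That level was high only in dTG_normal replicates 2 and 3. Fetal sex and a dTG_normal mean resting mainly on replicate 1 therefore cannot be told apart here.

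**Figure D3:**
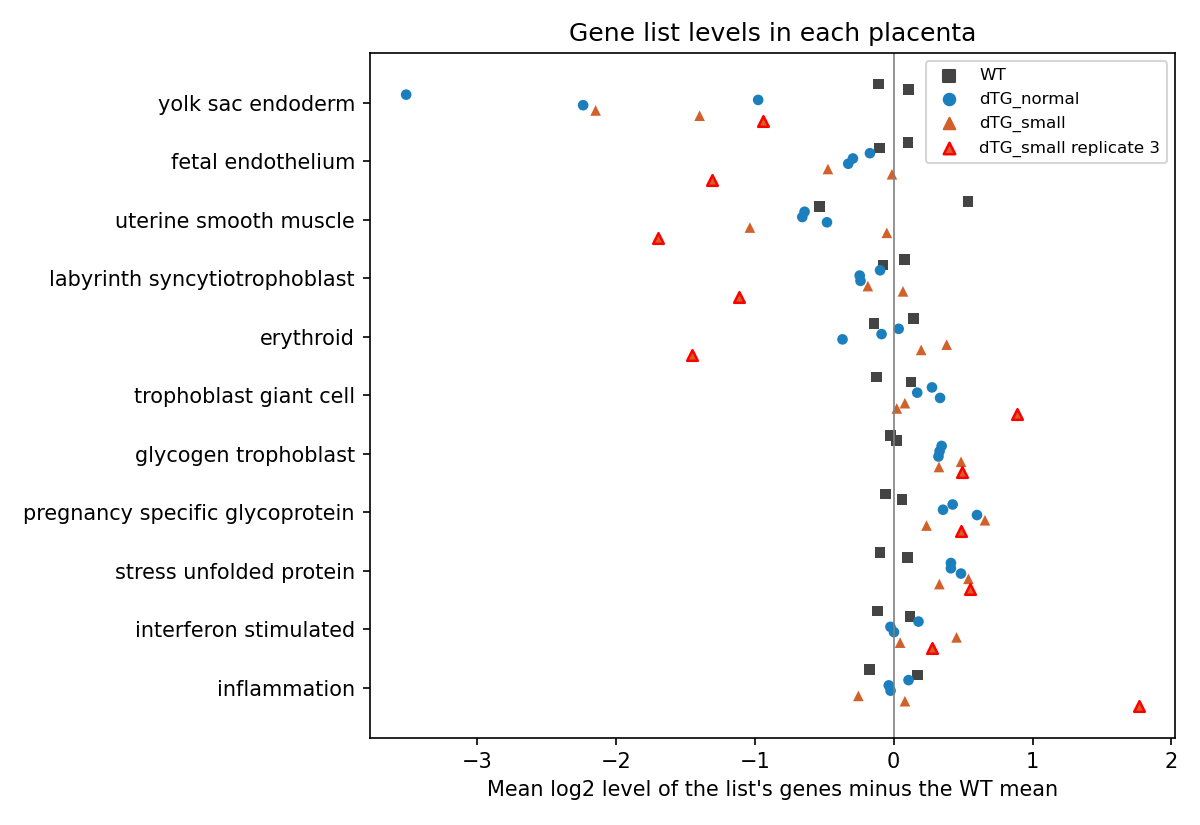
Each mark is a placenta (squares WT, circles dTG_normal, triangles dTG_small, dTG_small replicate 3 edged in red), and the horizontal axis gives the mean log2 level of a list's genes minus the WT mean. Yolk sac endoderm genes lie from -3.51 to -0.94 in the 6 dTG placentas, and dTG_small replicate 3 lies apart for labyrinth (-1.11), endothelium (-1.31) and inflammation (1.76).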

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

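Chosen after the result was seen were the tests of slide order and of the correlation within groups.

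The placenta of dTG_small replicate 3 stood apart from the other 5 transgenic placentas in 9 of 34 list scores, and no other of the 6 stood apart in any (chance alone sets apart about 1 in 20). Some lists share genes, such as giant cells with the prolactin family and endothelium with angiogenic factors, so the 9 scores are not independent. A list score is the mean log2 level of a list's genes minus the WT mean. The scores of this placenta were -1.11 for labyrinth syncytiotrophoblast, -1.31 for fetal endothelium, -0.74 for nutrient transport, -0.60 for imprinted genes and -0.35 for angiogenic factors. They were 0.885 for giant cells, 0.83 for the prolactin family, 0.81 for macrophages and leukocytes and 1.76 for inflammation. The labyrinth list had 15 of 18 genes below the other dTG placentas, with a median difference of -0.44. Single genes went far: Synb, a fusion gene of the labyrinth, was at -2.19 in this placenta and between 4.37 and 5.14 in the other 7. Slc13a4, a transporter gene also expressed in the labyrinth, was at 0.26 against 5.82 to 6.56. The fixed lists hold Slc13a4 under yolk sac endoderm and not under labyrinth, so it also lowers the yolk sac score of this placenta. Prl3d1, a giant cell hormone, was at 8.10 against 4.47 to 5.32, and the inflammatory gene Ccl2 at 3.10 against -0.69 to 0.17. These genes were chosen after their values were seen.

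Low signal on that array is argued against by the 56.2% of its spots well above background, within the range of the other arrays. Degraded RNA stays open, because this share measures signal and no measure of RNA integrity was examined. Whether the sample held less labyrinth, fetal vessel and blood tissue stays open: of the second lists fixed for this test, endothelium (median -0.72, 12 of 12 below 0) and red cells (-0.99, 12 of 16) were lower than in the other dTG placentas, but the labyrinth list, with the highest of the 3 medians, was at -0.18 (6 of 12). A placenta sampled without part of its labyrinth, or one with an inflamed or damaged labyrinth, may each give this pattern. A biological difference of small embryos was not shared by the other dTG_small placentas, and no test here separates these accounts.

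In 5 lists the transgenic groups differed from each other at camera's preset correlation, tested as the difference itself. None of the 5 passed with an estimated correlation (adjusted p = 0.858 for each), and no gene in them passed. The medians of dTG_small minus dTG_normal were -0.31 for endothelium, 0.92 for yolk sac endoderm, 0.17 for the cell cycle, 0.20 for interferon-stimulated genes and 0.44 for inflammation. The endothelium, yolk sac and inflammation calls ended without dTG_small replicate 3 (adjusted p = 0.907, 0.0985 and 0.168), with medians of -0.030, 0.48 and -0.22. The other median it moved was that of the cell cycle (0.10). Medians also moved by over 1.5 times without dTG_normal replicate 1 (yolk sac 0.18), dTG_normal replicate 2 (yolk sac 1.62), dTG_normal replicate 3 (cell cycle 0.092), dTG_small replicate 1 (interferon 0.091, inflammation 0.82) and dTG_small replicate 2 (interferon 0.31, endothelium -0.55). Of the 10 splits of the 6 dTG placentas into 3 and 3, all 10 gave at least as many lists. The real split gave 5, the fewest, and the other splits gave 9 to 17. This met the rule set beforehand for lists that arise by chance. The count of 5 lists is therefore no evidence of a difference by embryo size. Too few splits exist for a share under 0.05, so this test could not have excluded chance. For single genes the real split gave 0 and the highest other 0, so a count of splits decides nothing there.

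Yolk sac endoderm genes were lower in all 6 dTG placentas, and by unequal amounts. Afp, with the highest signal among their probes in WT, was at 8.46 and 8.54 in WT, at 5.11, 7.85 and 6.71 in dTG_normal replicates 1 to 3 and at 6.76, 7.39 and 8.18 in dTG_small replicates 1 to 3. A second list of such genes, fixed to test for less yolk sac endoderm in the dTG samples, was also lower, as that account predicts. Its median was -0.80 (16 of 18 below 0), with a camera p of 2.19e-08, and 0.0457 with an estimated correlation. Neither p is adjusted over the 5 hypothesis lists, and the first yolk sac list did not pass with an estimated correlation. The test of yolk sac content that varies between dissections gave a median correlation of 0.95 between list members within groups. By comparison, 1000 random lists reached at most 0.44. Markers of 1 cell type vary together whatever makes its amount vary, so this correlation cannot single out dissection. Dissection, the transgene, the dam and the place on the slide all stay open and untested as accounts, since WT came from 1 dam.

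Of the 8 columns in the deposited value table, 5 matched best the scanner file of another sample, and 3 their own. In slide order, 8 of 8 columns matched the array at the same place, as value table columns set in slide order would. The same match would come about if the placentas lay on the slide in sample order and the scanner files were mislabelled. It therefore does not tell these accounts apart. Whether the scanner files carry the wrong group labels was tested with the 28 splits of the arrays into 2 and 6. Only 1, that by the scanner files, gave as many genes (2176 in a fit of these groups, and the highest other gave 6). This split also sets apart the arrays at place 1 of the slide lines. The count thus cannot tell group labels from slide place and leaves the question open. Wrong labels between the transgenic groups stay open and cannot be told apart, because neither the value table labels nor those of the scanner files gave a gene between them (0 each). No biological explanation was tested for this pattern.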

How the results depend on the processing

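Chosen after the data were seen were the value table with columns matched to the scanner files, the slide line as a block, the yolk sac covariate and the CT-repeat filter. Where a value below differs from the report, the cause was not tested unless given.

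For the genes of largest change and the leading members of the shifted lists, 3505 values under alternatives kept direction and side of the threshold, 646 kept direction but no longer passed, 94 newly passed and 26 reversed. Among these genes for dTG against WT, the calls lost most often were Sfmbt2 (19 of 27 alternatives), Tas2r113 (17 of 26) and Hsp90b1 (16 of 27). Without CT-repeat probes the counts of genes were 1338, 515, 649 and 0, near those of the report. At the preset correlation, yolk sac endoderm, the unfolded protein response and the pregnancy-specific glycoproteins passed in each comparison with WT whichever placenta was left out.

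Leaving out each placenta in turn gave 15 to 1860 genes for dTG against WT, 18 to 488 for dTG_normal against WT, 3 to 1031 for dTG_small against WT and 0 to 4 for dTG_small against dTG_normal, with 4 to 10, 3 to 9, 6 to 11 and 3 to 12 lists. Where 1 WT placenta remained, it was assumed to vary like the other groups. Between the transgenic groups, 4 genes passed without dTG_normal replicate 1 and 2 without dTG_small replicate 2.

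In the order dTG, dTG_normal and dTG_small against WT, the median of each array gave 781, 325 and 386 genes, with 4 lists for dTG and 3 for dTG_normal. Quantile normalization gave 335 genes for dTG_normal and 337 for dTG_small, and 3 lists for dTG_normal. The normexp background with the 75th percentile gave 8 lists for dTG_normal against WT and 14 between the transgenic groups, and with quantile normalization 9 between them. With no filter on dim probes there were 416, 132 and 86 genes, and 9 lists for dTG_normal. Each probe on its own gave 12 lists for dTG against WT and 10 between the transgenic groups.

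A fit of only the groups compared gave 2176 genes for dTG and 2 for dTG_small against WT, and 8 lists for dTG_normal. The eBayes step with trend and robust gave 953 genes for dTG_normal and 1374 for dTG_small. Array weights gave 2897, 1524 and 1285 genes, and 3 lists between the transgenic groups. The replicate block gave 17, 2 and 2 genes; replicate numbers do not pair the placentas, as same-number pairs correlated at -0.14 to 0.19 over 7 pairs. The Y-linked level as covariate gave 94 genes for dTG, 9 for dTG_normal and 1 between the transgenic groups, with 3 lists for dTG_normal and 1 between the transgenic groups. It was high only in dTG_normal replicates 2 and 3, so in this fit the dTG_normal mean rests mainly on replicate 1. The slide line as block gave 815, 196 and 172 genes. The yolk sac level as covariate gave 1, 0 and 5 genes, and 2, 2 and 6 lists, with 3 between the transgenic groups. That level separated WT from dTG, so this covariate takes up much of the genotype difference. With an estimated correlation 0 lists passed in each of the 4 comparisons, and fry called 4 lists for dTG, 3 for dTG_small against WT and 0 between the transgenic groups. A block by slide or scan was not run, since all arrays shared 1 slide and 1 scan.

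The deposited value table as labelled gave 0, 0 and 0 genes and 0, 1 and 1 lists against WT, and 9 lists between the transgenic groups; with its columns matched to the scanner files it gave 335 genes for dTG_small and 3 lists for dTG_normal. Of its labels, 5 of 8 differ from that of the best-matching scanner file, and which are right stays open. Under the value table's labels named genes reversed, and none of them reversed with the columns matched. For dTG against WT these were Rab17 0.022, Igfbp3 0.013, Apob 0.015, Trf 0.044 and Apoc2 0.56. For dTG_normal they were Cdh5 -0.0018, Apob 0.35, Trf 0.19 and Alb 1.59, and for dTG_small Apoc2 0.21. Between the transgenic groups they were Dop1a -0.15, Prl5a1 -0.69, Esam 0.042, Alb -0.52, Ttr -0.40, Amn -0.59, Apoa2 -0.34, Ccnb2 -0.65, Gbp2 -0.29, Oasl1 -0.11, Mx2 -0.26 and Tnfaip3 -0.14. Of the list calls, yolk sac endoderm pointed the other way under these labels in all 4 comparisons, and interferon-stimulated genes between the transgenic groups. Endothelium and inflammation did so between the transgenic groups without dTG_small replicate 3. The other gene reversals, also between the transgenic groups, were Serpina3i -0.23, Dop1a -0.014 and Il1rn -0.11 with normexp and the 75th percentile, and Serpina3i -0.019 with normexp and quantile normalization.

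Signal over background limits the genes that a group did not show above it; their differences are given only as bounds.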

Other observations

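Chosen after the result was seen were the tests of CT repeats, of their length and of GC content; the seed-target test was planned before its result was seen. The genes of the next paragraph were chosen after their values were seen.

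The embryonic globin gene Hbb-y was at 4.54 and 4.13 in dTG_small replicates 1 and 3 and between 0.55 and 1.99 in the other 6 placentas. The granzyme genes Gzme and Gzmg were lowest in dTG_small replicate 1, at 3.42 against 4.11 to 5.09 and at 1.87 against 2.73 to 3.81 in the others. The erythroid and natural killer list scores set no placenta apart. The interferon-stimulated genes Isg15 and Rsad2 were highest there, at 5.98 and 3.73, against at most 5.28 and 2.93 in the other 7. Without dTG_small replicate 3 the lists that differed between the transgenic groups at camera's preset correlation were giant cells (median -0.11, adjusted p = 0.0019), natural killer cells (-0.57, 0.00292), erythroid cells (0.24, 0.0246), the cell cycle (0.10, 0.0223) and interferon-stimulated genes (0.17, 0.000633). No gene in them passed, and with an estimated correlation the lowest adjusted p of these lists was 0.755.

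Of the 12 largest rises in dTG, 4 were those of the receptor genes Mc3r, Olfr1466, Tas2r113 and Gpr157, whose probes hold the repeat TCTCTC, as do 2.41% of the genes tested. The longest runs of CT or TC units in these 4 probes were 7, 9, 13 and 11 bases, in that order. Among the other 558 genes with this repeat, the median excess over probes of like level was 0.16, short of the 0.2 set for the test. The excess rose with length, to 0.34 with CTCTCTC (171 genes), 0.55 with TCTCTCTC (78 genes) and 0.90 with CTCTCTCTC (48 genes). Cross-hybridisation to CT-rich transcripts may give such a rise. Probes with the opposite repeats GAGAGAGA and GAGAGAGAG had an excess of -0.24 and -0.45. In all, 14 repeats were looked at. The 135 chemosensory receptor genes without the repeat still had a median excess of 0.26. Of them 17 passed upward, against 1101 of all 23291 genes tested. This class was not among the fixed lists, its excess was not tested, and Mc3r and Gpr157 are not in it. Probes with longer CT repeats thus had larger differences, but these values do not decide how much of the 4 rises the repeats account for. GC content stays open: its Spearman correlation with the difference across genes was 0.093, weak and too near the bound of 0.1 to exclude it. Whether the 4 receptor transcripts rose may need another probe to settle.

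A further hypothesis was that targets of microRNAs with the AAGUGC seed, which members of C19MC carry, have lower mRNA in dTG. The 25 genes taken as targets were listed from general knowledge and not checked against a source, which limits what the test can show. They had a median difference of -0.07 from WT, with 15 below 0 and a camera p of 0.0194, under the 0.05 set beforehand (0.0323 adjusted over 5 hypothesis lists), but 0.237 with an estimated correlation. The p ran from 0.00907 to 0.0660 on leaving out each placenta, the highest without dTG_small replicate 1. Ccnd2 passed upward (0.81), and Txnip (-0.68) and Cdkn1a (-0.50) downward. A small lowering of these targets is thus possible and not established, and the microRNAs themselves were not measured. Of the other 4 lists, the adjusted p for dTG against WT was 0.00278 for endothelium, 0.0515 for labyrinth, 0.0646 for red cells and 1.09e-07 for yolk sac. With an estimated correlation the camera p, not adjusted over the 5 lists, was 0.311, 0.0842, 0.411 and 0.0457 in the same order.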
